A study of Mus musculus with 7 samples.

How the data were processed

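Messenger RNA was sequenced from pancreatic islets of 7 db/db mice. Per the labels' protocols, the mice received an adeno-associated virus (AAV) that encodes either green fluorescent protein (GFP) or adipsin, islets were taken after 4 weeks and kept in culture for 12 hours, and libraries were made with a stranded mRNA kit. Each mouse gave 1 library, and the labels state that the mice are separate biological replicates. Per the submitters' processing notes, reads were aligned with STAR and the genome build is mm10 (GRCm38). The STAR version, the counting program, its strand setting and the annotation release are not given in the sources used here, so reads of a gene and of a gene on the opposite strand at the same place cannot be told apart with certainty.

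The values are the read counts per gene that the authors deposited as 1 table with a column per library. They are whole numbers that were not normalised, and no sample column was left unused. The table has 51912 Ensembl gene identifiers, of which 51719 were matched to GENCODE mouse release M21 (release number 21, GRCm38) for symbols and coordinates, 193 had no symbol, and 22479 had no count in any library. Total counts per library ran from 29601707 to 43997400. A CPM value is a count scaled by the library total and by the scaling factor of the library described below, in the usual unit of that name. By the library total alone, 3 counts, taken as the floor for a count of 0, correspond to between 0.0682 and 0.101 CPM.

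Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, libraries were scaled by the trimmed mean of M values (TMM), and a negative binomial model with an intercept and the treatment was fitted by robust quasi-likelihood. P values from edgeR's two-sided quasi-likelihood F test were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are AAV-Adipsin over AAV-GFP on the log2 scale, with the standard error (SE) obtained from the F statistic. Log2 CPM values used for separation of groups, principal components and list scores carried a prior count of 2. Exact permutation tests over the 35 ways to divide 7 libraries into 3 and 4 were two-sided. The smallest p they can give is 0.0571, so they cannot reach 0.05 in this design. Intervals on counts are 95% intervals derived from Clopper-Pearson limits and cover counting error only, since the reads carry no molecular identifiers.

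Gene lists for islet cell types, other pancreatic and immune cell types and cellular programmes were written before the data were examined, as were the tests, the alternatives other than those said to be added, and the rule for the genes named. In each direction the rule takes up to 12 genes past the threshold with the largest change, complete separation of the groups and a mean log2 CPM of at least 1. It leaves out symbols that start with Gm and a digit or end in Rik, and genes without a symbol. Where fewer than 5 pass, it takes the 5 with the smallest p that meet the other conditions. It adds 15 genes fixed in advance and up to 4 members with the smallest p from each list. Lists with at least 3 members tested were compared with all other genes by camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over 31 lists. Camera with an estimated correlation and fry, which tests a list without reference to other genes, were run beside it. A list score is the mean log2 CPM of its members in a library.

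The alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, quasi-likelihood without robust estimation, the replicate number as a block, the style of the sample descriptions as a batch, an acinar score as a covariate, thinning of counts to the smallest library, other thresholds, and removal of each library in turn or of both libraries described by a treatment name. Added after the data were seen were DESeq2 with description style as a batch and camera with an estimated correlation in that model. The tests were tried on simulated counts with the means and library sizes of these data, in which 200 of 16281 genes were changed. In this simulation of AAV-Adipsin against AAV-GFP, edgeR recovered 68% of the 2-fold and 94% of the 4-fold changes, with 5.26% of its calls false. DESeq2 recovered 79% and 95%, with 19.8% of its calls false, and limma-voom recovered 66% and 93%, with 4.79% false. The simulated genes were drawn independently of each other and without any difference by description style. The 200 changed genes were drawn only from genes above a cutoff of mean expression. With fewer changed genes, the adjustment over all genes demands a smaller p of each. These rates therefore need not hold for the real libraries, and they do not give the power where few genes change. No library was left out of the main comparison.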

Results

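Islet transcripts were measured in db/db mice, which lack a functional leptin receptor and become obese and diabetic. The mice had received an AAV vector for adipsin or for GFP. Adipsin, also called complement factor D, is a serine protease secreted mainly by fat cells that acts in the alternative pathway of complement, and its gene in the mouse is Cfd. The comparison asks which islet transcripts differ under raised systemic adipsin, 1 month after the vector was given, when blood glucose did not yet differ between the groups per the labels. There were 4 AAV-GFP and 3 AAV-Adipsin libraries, each from a separate mouse. Total counts were 36043950 ± 6795844 in AAV-GFP (SD, n = 4) and 36292314 ± 4387198 in AAV-Adipsin (SD, n = 3). Ins2, one of the insulin genes, took 11.0% to 13.8% of the counts of a library, and the 10 most abundant genes took 21.5% to 25.1%. Counts of the 26 acinar genes, which mark the digestive-enzyme cells around islets, made up 0.351% to 2.28% of a library, at 1.12 ± 0.843% in AAV-GFP (SD, n = 4) and 0.879 ± 0.700% in AAV-Adipsin (SD, n = 3). All 7 libraries had between 1591 and 3541 counts of the Y-linked gene Ddx3y and at most 3 of Xist.

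The libraries also differ in how they are described. In each group, 1 library (replicate 1) is described by its treatment name and the others by a db number, which makes 2 libraries against 5. These 2 libraries lay together at one end of the first principal component, which held 41.3% of the variance between libraries. Description style accounted for 72.7% of that component and treatment for 0.609%. Over all genes, description style accounted for 36.1% of the variance and treatment for 11.4%. Treatment accounted for 57.6% of the third component, which held 14.0% of the variance. Any division of so few libraries takes some share of the variance. The share of a random division was not computed, so these shares do not by themselves show an effect of treatment. The correlation of log2 CPM across genes was highest between AAV-GFP replicate 1 and AAV-Adipsin replicate 1, at r = 0.994, against 0.970 to 0.993 between libraries of the same treatment. Genes are not independent replicates, so these correlations describe the libraries only. Because both treatments occur in both description styles, values within each style are given below for Cfd, Dusp26, the lists called by camera, and some other genes and lists.

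**Figure D1:**
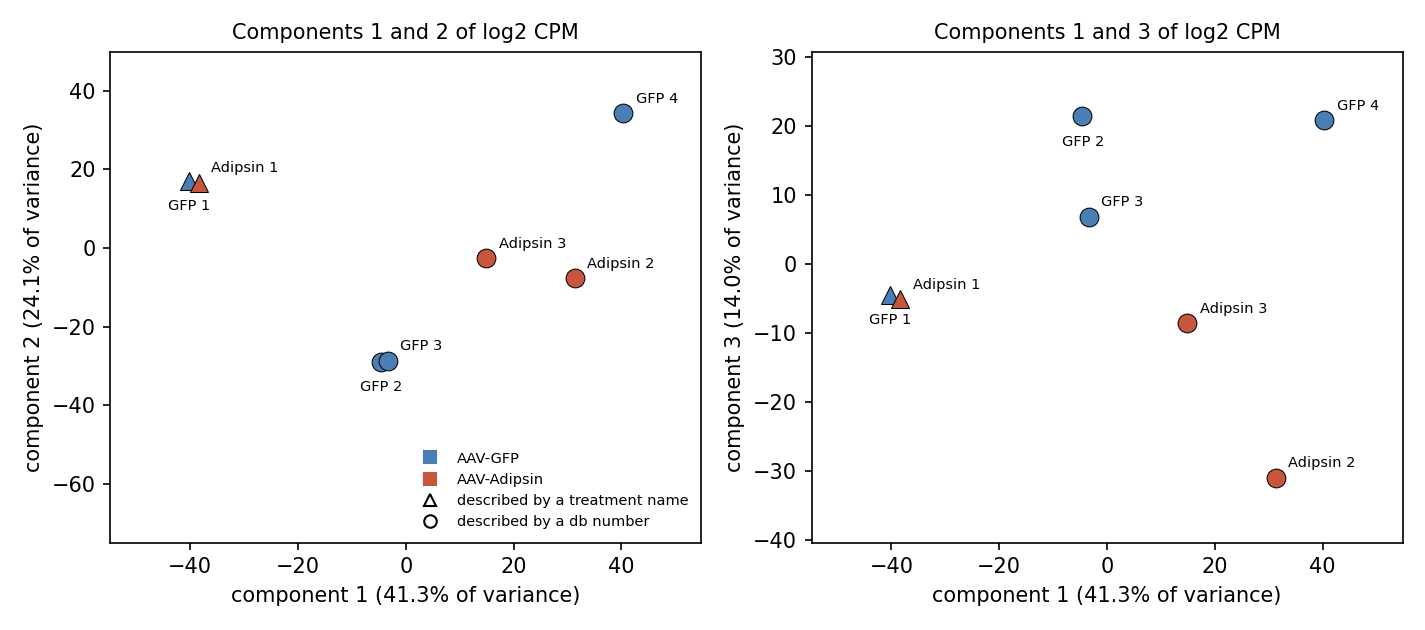
Principal components of log2 CPM for the 7 libraries, with component 1 (41.3% of variance) on both horizontal axes and component 2 (24.1%) or 3 (14.0%) on the vertical axes. Colour shows the treatment and shape the description style: the 2 triangles, described by a treatment name, lie together at the left in both panels.

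Cfd, the transcript that the vector encodes, was the 1 gene past the threshold. It had 3965, 839 and 1481 counts in the 3 AAV-Adipsin libraries and 1, 0, 0 and 0 counts in the 4 AAV-GFP libraries, so it was higher in 3 of 3. Expression was 55.5 ± 41.3 CPM in AAV-Adipsin (SD, n = 3) against 0.00556 ± 0.0111 CPM in AAV-GFP (SD, n = 4). The 6285 counts in one group against 1 in the other give a ratio of rates of 8323, with a 95% interval from 1493 to 328779 for counting error alone. The gene (ENSMUSG00000061780) lies on chromosome 10 from 79890853 to 79892655 of GRCm38, on the plus strand. Counts per gene do not separate transcripts of the vector from transcripts of the animal's own gene. The log2 fold change fitted by edgeR, 12.38 (SE 0.93), depends on the prior count, and its adjusted p was 0.0420. Both description styles showed the difference, with log2 CPM higher by 10.37 in the pair described by treatment names and by 9.15 among the libraries described by db numbers. With description style as a batch, the edgeR adjusted p was 3.39e-06. The call by edgeR was lost without AAV-GFP replicate 1 (adjusted p = 1.00), 2 (0.241), 3 (0.455) or 4 (0.525) or AAV-Adipsin replicate 3 (0.0634), without both libraries described by a treatment name (0.0734) and without a filter on low counts (0.667). It was not made by limma-voom (0.834). DESeq2 gave an adjusted p of 1.15e-18, or 1.41e-34 with description style as a batch.

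**Figure D2:**
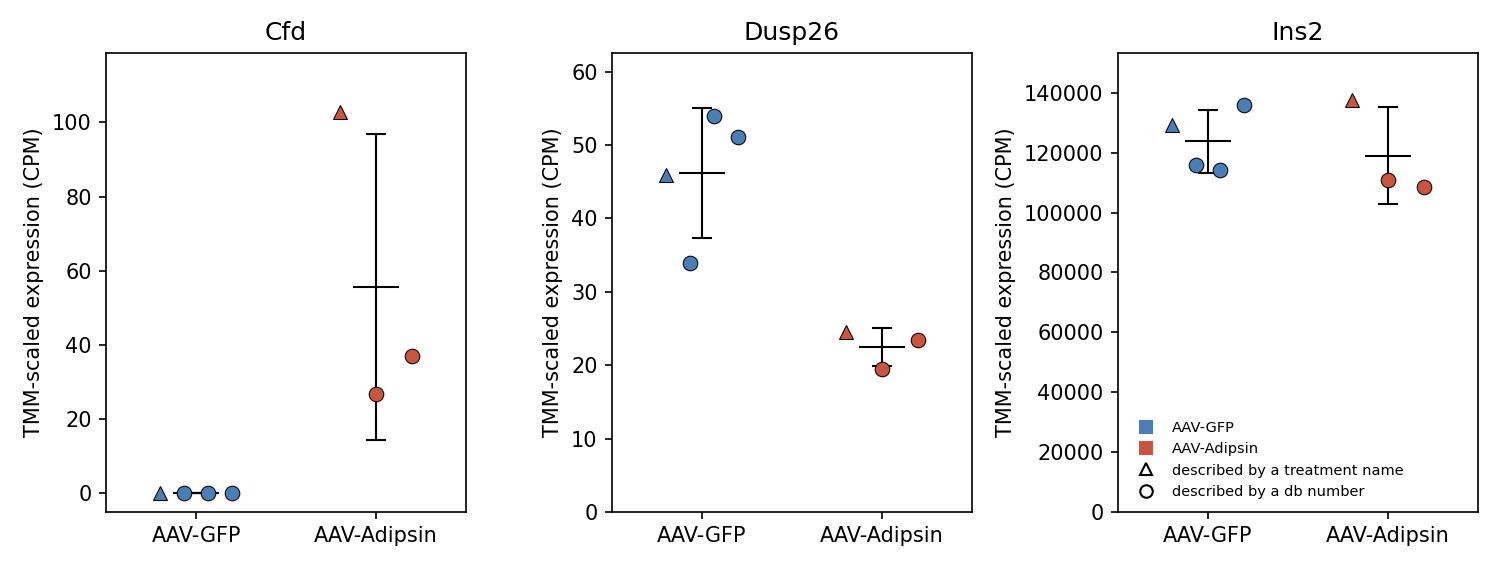
TMM-scaled expression of Cfd, Dusp26 and Ins2 in CPM, with 1 point per library, a horizontal bar at the group mean and whiskers of 1 SD. Cfd was at 0.00556 CPM on average in the 4 AAV-GFP libraries and 55.5 in the 3 AAV-Adipsin libraries, and Dusp26 was lower in all 3 AAV-Adipsin libraries than in any AAV-GFP library.

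Dusp26, a dual-specificity protein phosphatase, had the next smallest p. It stood at 22.5 ± 2.61 CPM in AAV-Adipsin (SD, n = 3) against 46.2 ± 8.88 CPM in AAV-GFP (SD, n = 4), lower in 3 of 3, and the exact permutation p was 0.0571, the smallest possible here. The log2 fold change was -1.04 (SE 0.16), with an edgeR p of 1.52e-04 that did not pass after adjustment (adjusted p = 1.00). DESeq2 called it, at -1.03 (SE 0.18) with an adjusted p of 4.10e-05, and again with description style as a batch, at -1.04 (SE 0.17) with an adjusted p of 7.89e-06. Of the 19 alternatives set before the data were seen, only 1, DESeq2, called Dusp26. Neither limma-voom nor edgeR with description style as a batch called it. Its log2 fold change ran from -1.15 to -0.94 over these 19. The difference in log2 CPM was -0.90 in the pair described by treatment names and -1.08 among the libraries described by db numbers. Dusp26 (ENSMUSG00000039661) lies on chromosome 8 from 31089471 to 31097047, on the plus strand. The published study of these islets singled it out on these samples, so its place here is not independent evidence. Of the 21 dual-specificity phosphatases tested, none passed over all genes. Adjusted over the list alone 1 passed, Dusp26 itself, and since the study chose it on these samples this count is not independent evidence either. As a list the phosphatases had a median log2 fold change of 0.00 and a mean of -0.01 (camera adjusted p = 0.556). Dusp14, at -0.28, and Dusp2, at 0.80 and under 0.3 CPM in each library, had the next smallest p among them and did not pass.

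Over the 16504 genes tested, 14216 of them protein coding, edgeR called 1 gene higher and 0 lower. At an unadjusted p under 0.05 there were 191 genes, 1.16% of those tested, where a uniform distribution of p would give 825. That count was 458 with description style as a batch, 492 without both libraries described by a treatment name and 448 without a filter on low counts. It was 328, 129, 125 and 570 without AAV-GFP replicates 1 to 4 in turn, and 525, 92 and 140 without AAV-Adipsin replicates 1 to 3. The groups did not overlap for 451 genes, or 2.73%, where chance gives 5.71%. DESeq2 called 4 genes: Cfd, Dusp26, Nyap2 and Xlr3a. Nyap2, which encodes a neuronal phosphoinositide 3-kinase adaptor, stood at 30.2 ± 5.92 CPM in AAV-Adipsin (SD, n = 3) and 18.8 ± 1.5 in AAV-GFP (SD, n = 4), with a DESeq2 adjusted p of 0.0354. Xlr3a, an X-linked gene with close copies between which the counting could divide reads, stood at 15.5 ± 5.57 and 5.69 ± 2.03 CPM, also with a DESeq2 adjusted p of 0.0354. In the pair described by treatment names Nyap2 differed by 0.31 and Xlr3a by 0.73 in log2 CPM, against 0.83 and 1.78 among the libraries described by db numbers. The other genes that the naming rule took for a small p and no overlap between groups did not pass in edgeR or DESeq2. On the higher side they were Nr1d1, a circadian repressor, at a log2 fold change of 0.47 (SE 0.11), and Piezo1, a mechanosensitive channel, at 0.75 (SE 0.17). On the lower side they were Cpne4 at -0.35, N4bp2l1 at -0.29, C1qtnf1 at -0.38 and Wee1, a cell cycle kinase, at -0.35. Without both libraries described by a treatment name, edgeR called 0 genes, limma-voom on all libraries called 0, and leaving out single libraries gave 0 or 1, as listed for Cfd.

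None of the genes of insulin production named here passed. Ins2 had a log2 fold change of -0.06 (SE 0.12) and Ins1 -0.01 (SE 0.21), although these 2 insulin genes are close copies whose reads the counting could divide, and the fitted sign of both turned under some alternatives, as did those of Iapp, Pdx1, Slc2a2, Ucn3 and Sst. Iapp, the amyloid peptide released with insulin, was at -0.11 (SE 0.15), the transcription factors Pdx1 at -0.02 (SE 0.08), Nkx6-1 at -0.18 (SE 0.09) and Mafa at -0.29 (SE 0.17), the glucose transporter Slc2a2 at -0.20 (SE 0.33) and the maturity marker Ucn3 at -0.06 (SE 0.35). The difference in the pair described by treatment names and that among the others were 0.19 and -0.50 for Mafa, -0.02 and -0.48 for Slc2a2, 0.20 and -0.39 for Ucn3, 0.09 and -0.15 for Ins2, 0.32 and -0.05 for Ins1, and -0.02 and -0.21 for Iapp. Aldh1a3, a marker of beta cell dedifferentiation, did not pass either, at -0.24 (SE 0.18). Gcg and Sst, the alpha and delta cell hormones, were at 0.16 (SE 0.14) and -0.06 (SE 0.22). Of 29 beta cell identity genes, 0 passed, over all genes or adjusted over the list alone. Camera placed this list lower than other genes (adjusted p = 0.0107) with a median of only -0.054 and 22 of 29 members below 0; the adjusted p was 0.816 with an estimated correlation. The smallest p in it belonged to Nkx2-2, at -0.27 (SE 0.10), with -0.06 in the pair described by treatment names and -0.34 among the others. The list score differed by 0.02 in the pair described by treatment names and by -0.13 among the others. Its call was lost without AAV-GFP replicate 1 (median -0.024, adjusted p = 0.205), 2 (0.0765) or 3 (0.0503) or AAV-Adipsin replicate 2 (0.0085, 0.712) or 3 (-0.030, 0.128), and its median was -0.097 without AAV-GFP replicate 4 and -0.12 without AAV-Adipsin replicate 1. The lists for granule exocytosis (adjusted p = 0.609), dedifferentiation (0.428), alpha cells (0.845), delta cells (0.638) and PP cells (0.609) were not called by camera.

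Lists of non-endocrine cells and of interferon genes had higher values in the AAV-Adipsin libraries, by camera with its preset correlation. All 19 macrophage genes were above 0, with a median log2 fold change of 0.44 (camera adjusted p = 2.5e-07), among them Mpeg1 at 0.66, Msr1 at 0.72 and Csf1r, the receptor for the macrophage growth factor, at 0.52, whose fitted value turned negative without AAV-Adipsin replicate 2 and which differed by -0.13 in the pair described by treatment names and by 0.65 among the others. Of 28 genes of interferon response and antigen presentation, 21 were above 0, with a median of 0.16 (camera adjusted p = 2.5e-07), led by the interferon-induced Ifit3 at 1.11 (SE 0.34) and Ifit2 at 1.18 (SE 0.37), which differed by 0.23 and 0.50 in that pair and by 1.34 and 1.33 among the others. The antigen presentation genes of this list stayed near 0. Tap1 was at 0.11 and Psmb8 at 0.09, and Tapbp at -0.10, H2-K1 at -0.07, H2-D1 at -0.06, Psmb9 at -0.01 and B2m at -0.004. Of 15 endothelial genes, 13 were above 0, with a median of 0.18 (1.57e-06), including the receptor Kdr at 0.29 and the transcription factor Erg at 0.27. Of 19 mesenchymal and stellate cell genes, 17 were above 0, with a median of 0.23 (1.03e-04). The 7 lymphocyte genes had a median of 0.55 (0.00617). These were weakly expressed transcripts such as Ptprc, at 4.13 CPM in AAV-Adipsin, and Ighm, at 0.603 CPM. The 30 genes of the beta cell disallowed list, taken as repressed rather than silent in beta cells, had a median of 0.18 (0.00864). In these 6 lists no member passed, over all genes or adjusted over the list alone. With an estimated correlation none of the 6 was called (adjusted p = 0.816 for each), and the correlation estimated between members ran from 0.144 for lymphocyte genes to 0.919 for mesenchymal genes. Fry called none of the 31 lists (smallest adjusted p = 0.908).

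The scores of these lists overlapped between the groups. The macrophage score was 3.66 ± 0.72 in AAV-Adipsin (SD, n = 3) and 3.30 ± 0.32 in AAV-GFP (SD, n = 4), with an exact permutation p of 0.457, and the mesenchymal score 3.63 ± 0.33 and 3.04 ± 1.09, with an exact p of 0.400. Within the pair described by treatment names the macrophage score differed by 0.03, against 0.55 among the libraries described by db numbers. The same 2 differences were 0.09 and 0.45 for the interferon list, 0.16 and 0.22 for the endothelial list, 0.22 and 0.77 for the mesenchymal list, 0.42 and 0.48 for the lymphocyte list, and -0.10 and 0.41 for the beta cell disallowed list. Without AAV-Adipsin replicate 2 the median of the macrophage list was -0.066 (adjusted p = 0.588), that of the lymphocyte list 0.11 (0.789) and that of the disallowed list -0.12 (0.191). The mesenchymal call was lost without AAV-GFP replicate 2 (median -0.022, adjusted p = 0.402) and with DESeq2 (0.0556). Its median was 1.08 without AAV-GFP replicate 4, 0.11 and 0.057 without AAV-GFP replicates 1 and 3, 0.14 without AAV-Adipsin replicate 2, and 0.59 with limma-voom. The interferon call was lost without AAV-GFP replicate 1 (0.0772) or AAV-Adipsin replicate 3 (0.0726). The interferon median was 0.11 without AAV-Adipsin replicate 3, 0.27 without AAV-GFP replicate 4 and 0.33 without AAV-Adipsin replicate 1, and the macrophage median rose to 0.67 and 0.68 without these last 2. The lymphocyte call was also lost without AAV-GFP replicate 1 (median 0.33, adjusted p = 0.418) or 3 (0.0655), without a filter on low counts (0.109) and with limma-voom (0.15, 0.0553), and its median was 0.84 without AAV-Adipsin replicate 1. The disallowed call was also lost without AAV-GFP replicate 1 (median 0.078, adjusted p = 0.423) or 2 (0.081, 0.590), and the median was 0.49 without AAV-GFP replicate 4 and 0.40 without AAV-Adipsin replicate 1. The endothelial list stayed past the threshold of camera without any 1 library (largest adjusted p = 0.0133), but its median was 0.093 without AAV-GFP replicate 2 and 0.32 without AAV-GFP replicate 4.

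**Figure D3:**
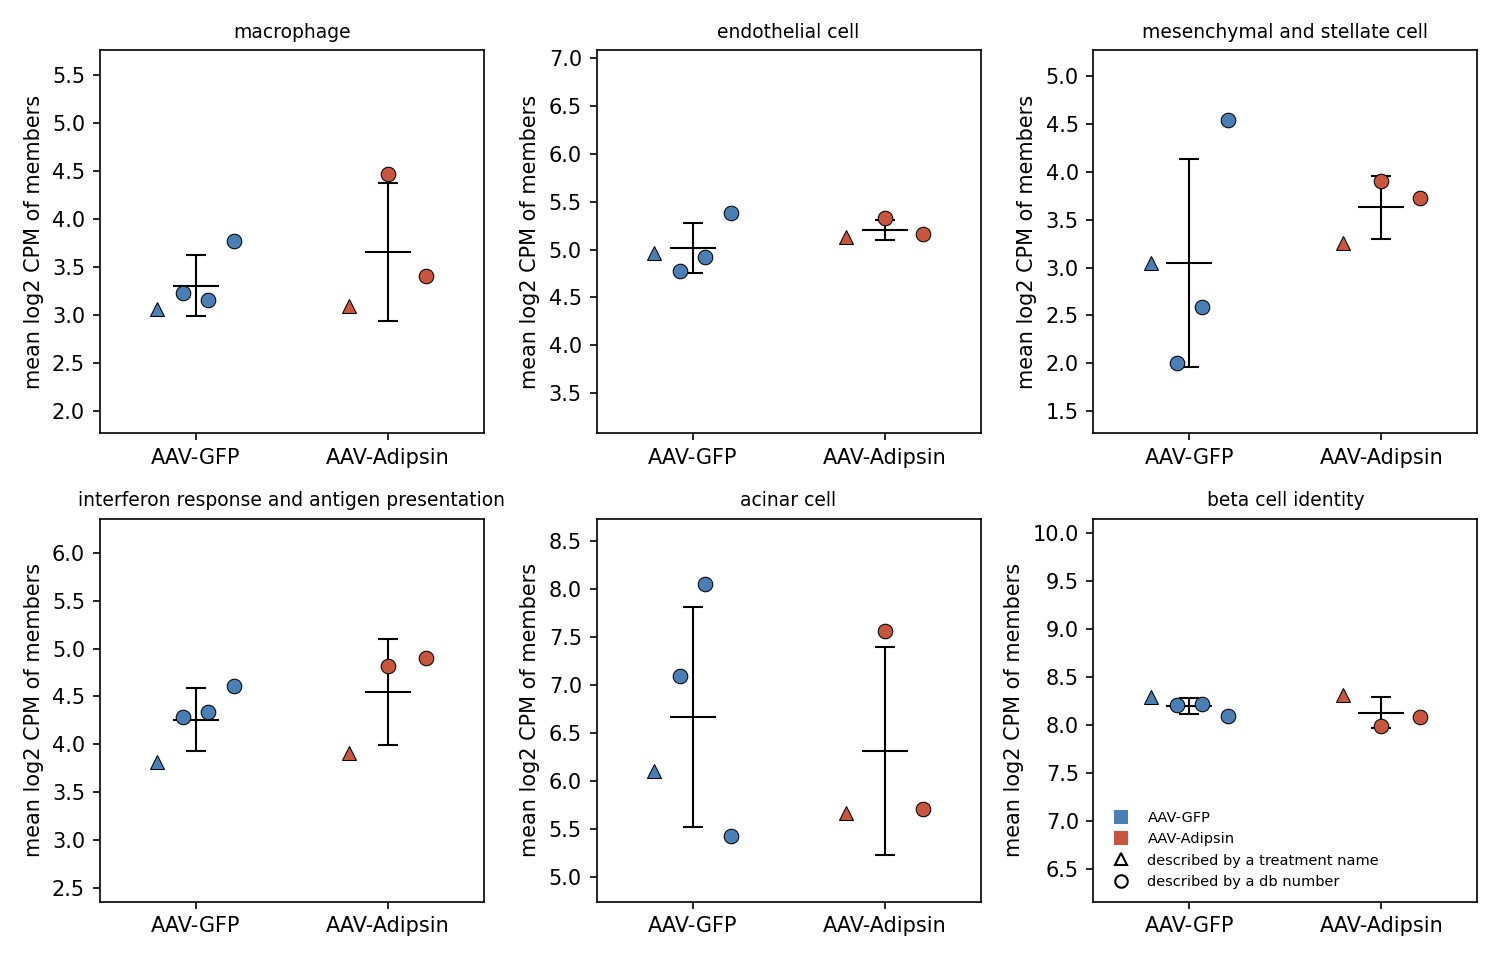
Mean log2 CPM of the members of 6 gene lists in each library, with a horizontal bar at the group mean and whiskers of 1 SD; every vertical axis spans the same range, in log2 units. The groups overlap in all 6 panels, and AAV-Adipsin replicate 2 holds the highest macrophage score of the 7 libraries, 4.47.

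Acinar and mitochondrially encoded genes had lower values in AAV-Adipsin. All 26 acinar genes were below 0, with a median of -0.36 (camera adjusted p = 0.00659), including the protease Ctrc at -1.18 (SE 0.60) and the elastase Cela1 at -0.66 (SE 0.83). All 8 mitochondrially encoded genes tested were below 0, with a median of -0.31 (7.0e-04), including mt-Nd4 at -0.46 (SE 0.36). With an estimated correlation the adjusted p was 0.816 for both lists, and 0 members passed, over all genes or adjusted over the list alone. The acinar score was 6.32 ± 1.09 in AAV-Adipsin (SD, n = 3) and 6.67 ± 1.15 in AAV-GFP (SD, n = 4), with an exact permutation p of 0.743. It differed by -0.43 in the pair described by treatment names and by -0.22 among the others, and the mitochondrial score by -0.10 and -0.30. Without AAV-GFP replicate 3, which had the highest acinar share, the acinar median was 0.30 (adjusted p = 0.358). The acinar call was also lost without AAV-GFP replicate 2 (0.0921) or AAV-Adipsin replicate 1 (0.627) or 3 (0.523), with description style as a batch (0.0645) and without both libraries described by a treatment name (0.126), although the median stayed at -0.31 and -0.28. It was -0.59 and -0.68 without AAV-GFP replicates 1 and 4, -1.36 without AAV-Adipsin replicate 2, and -0.067 and -0.049 without AAV-Adipsin replicates 1 and 3. The mitochondrial call was lost without AAV-GFP replicate 4 (median -0.070, adjusted p = 0.302), the library with the highest mitochondrial share at 2.67%, or AAV-Adipsin replicate 1 (-0.16, 0.224), and its median was -0.47 without AAV-GFP replicate 1 and -0.53 without AAV-Adipsin replicate 3.

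No complement gene other than Cfd passed. C3, the central component of the cascade, stood at 23.6 ± 12.0 CPM in AAV-Adipsin (SD, n = 3) and 18.6 ± 7.56 in AAV-GFP (SD, n = 4), with a log2 fold change of 0.34 (SE 0.44). C3ar1, the receptor for the C3a fragment that adipsin activity helps to release, stood at 5.97 ± 5.31 and 3.32 ± 0.85 CPM, with 0.84 (SE 0.53). Neither passed, and AAV-Adipsin replicate 2 alone had 12.0 CPM of C3ar1. Without that library the fold changes were -0.03 for C3 and -0.16 for C3ar1. The 20 complement genes tested had a median of 0.07 (camera adjusted p = 0.113), with 0 members past the threshold over all genes or adjusted over the list alone. With description style as a batch the list was called by camera (0.0223), at an adjusted p = 0.843 with an estimated correlation. It was also called without both libraries described by a treatment name (median 0.14, adjusted p = 0.00127), without AAV-GFP replicate 4 (0.61, 1.06e-05) and without AAV-Adipsin replicate 1 (0.26, 9.81e-05), and its median was -0.10 without AAV-Adipsin replicate 2. Its score differed by -0.06 in the pair described by treatment names and by 0.32 among the others. The list of NF-kB and acute inflammation genes had a median of 0.18 (0.217) and was called with description style as a batch (0.00385), at an adjusted p = 0.843 with an estimated correlation. It was also called without both libraries described by a treatment name (0.34, 2.03e-04), without AAV-GFP replicate 4 (0.58, 1.38e-05) and without AAV-Adipsin replicate 1 (0.63, 1.22e-06). Its median was -0.097 without AAV-GFP replicate 1, and -0.23 and -0.020 without AAV-Adipsin replicates 2 and 3. Its score differed by -0.09 in the pair described by treatment names and by 0.56 among the others.

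With all 7 libraries the other lists were not called by camera. Those with the smallest adjusted p were Schwann cells (0.0880), nuclear-encoded oxidative phosphorylation (0.0880), cholesterol synthesis (0.154), cell cycle (0.179) and adipocytes (0.215). Several of the other lists were called when 1 library was left out: Schwann cells without AAV-GFP replicate 4 (4.59e-04) or AAV-Adipsin replicate 3 (0.0115), nuclear-encoded oxidative phosphorylation without AAV-GFP replicate 2 (0.0342) or 3 (0.00373), and cell cycle without AAV-GFP replicate 3 (0.0200). Cholesterol synthesis was called without AAV-GFP replicate 1 (median -0.22, adjusted p = 3.40e-07) or AAV-Adipsin replicate 2 (-0.23, 5.15e-06) or 3 (-0.13, 0.0131), and its median was 0.085 without AAV-Adipsin replicate 1. Genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, had a median of -0.01 (adjusted p = 0.476), with Dnajb9 at -0.13 and Herpud1 at -0.19, and genes of apoptosis and p53 a median of -0.05 (0.682), with Apaf1 at 0.23 and Xiap at 0.13. Glycolysis (0.428), ribosomal proteins (0.428), duct cells (0.476), immediate early genes (0.601), heat shock (0.609), fatty acid synthesis (0.682) and hypoxia response (0.984) completed the 31 lists. Of these, ribosomal proteins were called without AAV-GFP replicate 4 (1.93e-04), glycolysis without AAV-GFP replicate 2 (0.0342), duct cells without AAV-Adipsin replicate 2 (median -0.14, adjusted p = 0.0183) and immediate early genes without AAV-Adipsin replicate 1 (0.00700). For adipocytes, delta cells, fatty acid synthesis, alpha cells and the dual-specificity phosphatases, the median, the mean and the direction of camera did not all have the same sign. Over all 31 lists and 582 members, 0 members passed in edgeR over all genes.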

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

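The tests of description style and of the share of beta cells for Dusp26, and of a single library and of the share of endocrine cells for the gene lists, and the counts of divisions that part the 2 libraries described by treatment names, were chosen after the results were seen.

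In the 4 AAV-GFP libraries, 12 of 173 named genes and lists had 1 library far from the other 3, by the size of the largest gap at either end over the whole range. Chance gives about 1 in 20. Cfd had a gap share of 1, from a single count in AAV-GFP replicate 1 against 0 in the others. AAV-GFP replicate 4 was the high library for 5 of the 12: Hhex, a delta cell transcription factor (0.901), the neurotrophin receptor Ngfr (0.900), the nuclear-encoded oxidative phosphorylation list (0.899), Jund (0.866) and the chemokine Cxcl5 (0.846). In AAV-GFP replicate 1, described by a treatment name, the low values were those of Vamp2 (0.950), Ptprb (0.896), Pparg (0.840), the cholesterol synthesis list (0.832) and its member Fdft1 (0.832). Crhr2 was low in AAV-GFP replicate 3 (0.861).

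The number of genes past the threshold was 1 for the labelled groups, and 3 of the 35 divisions of the 7 libraries into 3 and 4 gave as many, so chance is not excluded for the count. The highest other count was 173, with AAV-GFP replicate 4 and AAV-Adipsin replicates 2 and 3 against the rest, and it was led by the acute-phase gene Serpina3n. A count so far above the real one points to a structure of the samples. This division and the other with calls, 15 genes, keep the 2 libraries described by treatment names together. Of the 20 divisions that part them, as the labelled groups do, 1 gave as many genes, the real one. The highest other count was 0. As 1 of 20 is the smallest share this count can give, it could not fall under 0.05 and decides nothing. The fitted log2 fold change of Cfd kept 0.980 of its size with the acinar score in the model, 0.997 with description style in the model and 0.976 after thinning. Each group holds 1 library described by a treatment name, so the design nearly fixed the value for description style.

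Dusp26 was lower in all 3 AAV-Adipsin libraries. The ratio of its log2 difference with and without description style in the model was 1.01. Each group holds 1 library described by a treatment name, so the design nearly fixed this ratio and it decides nothing. The log2 CPM of Dusp26 differed by -0.90 in the pair described by treatment names and by -1.08 among the other libraries. The difference was therefore not confined to 1 style. Complete separation of the groups already fixed the sign of both values, and the pair holds 1 library of each treatment. These values are thus no separate test of a batch that follows description style. A lower share of beta cells is argued against, since 0.930 of the difference remained relative to the beta cell identity score. Chance is not excluded: in 13 of 35 divisions of the libraries, the real one included, some gene other than Cfd had a p as small as the 1.52e-04 of Dusp26, down to 8.69e-07, and 5 of these 13 are among the 20 that part the 2 libraries described by treatment names. An effect of adipsin on Dusp26 may remain as a hypothesis, which these libraries, from which the gene was first chosen, cannot test independently.

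Macrophage, endothelial, mesenchymal and interferon lists were higher in AAV-Adipsin by camera with its preset correlation, and none of the 4 was called with an estimated correlation (adjusted p = 0.816 for each). Of the 35 divisions, 24 called at least as many lists as the 9 called here and the highest other called 20 (13 and 17 among the 20 that part the 2 libraries described by treatment names), so chance is not excluded. Without AAV-Adipsin replicate 2 the differences in score kept a median of 0.600 of their size over the 4 lists, and that of macrophages went from 0.35 to -0.05, so it remains open how much of the pattern this library carries. A lower share of endocrine cells might raise all non-endocrine markers, but the acinar score differed by -0.35 with an SE of 0.85, which decides nothing. A response to adipsin, as the biological explanation given by the design, cannot be told apart from these 2 with the libraries at hand.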

How the results depend on the processing

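The 2 alternatives that add description style to DESeq2 and to camera with an estimated correlation were chosen after the data were seen. The number of genes past the threshold was 1. It was 0 without a filter on low counts, with limma-voom and without both libraries described by a treatment name, 4 with DESeq2 and 5 with DESeq2 and description style as a batch, where Oasl2 was added. Leaving out single libraries gave 0 to 1. The log2 fold change of Cfd kept its direction in all 19 alternatives set before the data were seen and was past the threshold in 11, and it was past it in the added DESeq2 fit (12.36). It was not past it without a filter (12.38), with limma-voom (11.30) and without both libraries described by a treatment name (13.09). Without a filter its unadjusted p rose from 2.55e-06 to 6.55e-05, and adjusted over only the genes that the filter keeps it was 0.374, so the number of genes tested does not account for the loss. With single libraries left out the log2 fold change ran from 11.57 to 13.92. The cause of these losses was not tested. The number of lists called by camera was 9 and became 15 with the replicate number as a block, 0 with fry, 0 with an estimated correlation, and 0 with an estimated correlation and description style as a batch. Replicate numbers 2 and 3 do not pair the samples: deviations of same-numbered libraries correlated at -0.01 and 0.01. For the replicates 1, which are the pair described by treatment names, they correlated at 0.66. The block left the number of genes at 1, and 1109 genes had an unadjusted p under 0.05 with it, against 191. With the block the medians were -0.085 for mitochondrially encoded genes (adjusted p = 0.157, against a median of -0.31), 1.15 for mesenchymal cells (0.23), 0.41 for beta cell disallowed genes (0.18), -0.76 for acinar cells (-0.36), -0.10 for beta cell identity genes (-0.054), 0.31 for endothelial cells (0.18) and 0.26 for interferon genes (0.16), with the value without the block in brackets. Replicate number 4 occurs only in AAV-GFP, so the block takes that library out of the comparison. Without a block, leaving out AAV-GFP replicate 4 gave medians near these. In the same order of lists they were -0.070, 1.08, 0.49, -0.68, -0.097, 0.32 and 0.27. The mesenchymal call was lost with DESeq2 (0.0556), the lymphocyte call without a filter (0.109) and with limma-voom (median 0.15 against 0.55, adjusted p = 0.0553), and the acinar call with description style as a batch (-0.31, 0.0645) and without both libraries described by a treatment name (-0.28, 0.126) against a median of -0.36. With limma-voom the mesenchymal median was 0.59. Without both libraries described by a treatment name the medians were -0.088 for beta cell identity genes, 0.29 for beta cell disallowed genes and 0.25 for interferon genes. With the acinar score as a covariate, which is built from the same genes, the median of the acinar list turned to 0.028. With single libraries left out, medians ran from -1.36 to 0.30 for acinar cells, -0.12 to 0.49 for beta cell disallowed genes, -0.14 to 0.15 for duct cells, -0.066 to 0.68 for macrophages, 0.11 to 0.84 for lymphocytes, -0.022 to 1.08 for mesenchymal cells, 0.093 to 0.32 for endothelial cells, 0.11 to 0.33 for interferon genes, -0.53 to -0.070 for mitochondrially encoded genes and -0.12 to 0.0085 for beta cell identity genes. Among lists not called they ran from -0.23 to 0.63 for NF-kB genes, -0.10 to 0.61 for complement and -0.23 to 0.085 for cholesterol synthesis, and the cause was not tested. Among single named genes, 2656 comparisons with an alternative kept their side of the threshold and direction where one was called, and 3 became past it. Among lists, 528 were kept, 32 became past it, 23 were no longer past it and 6 turned. Depth limits the values of transcripts near the floor, such as Cfd and the lymphocyte gene Ighm in AAV-GFP.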

Other observations

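The contrast by description style was examined after the libraries had been seen to separate by it, and the tests of its genes, of other pairs of libraries and of macrophages were chosen after that separation was seen.

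The 2 libraries described by treatment names, 1 of each treatment, had low levels of inflammatory transcripts that the 5 libraries described by db numbers expressed. Nos2, the inducible nitric oxide synthase, averaged 0.163 CPM in the pair and ranged from 21.4 to 34.9 CPM in the other 5. The chemokines Cxcl1 and Ccl20 averaged 0.424 and 0.0352 CPM in the pair, against ranges of 5.52 to 11.8 and 3.22 to 4.33 CPM. Targets and regulators of NF-kB signalling were lower in the pair too: Birc3 by a log2 difference of -2.71 (SE 0.14), Tnfaip3 by -1.86 (SE 0.09), the inhibitor Nfkbia by -1.66 (SE 0.11) and Relb by -1.45 (SE 0.07). In an edgeR model that also held treatment, 1606 of 17024 genes passed, 679 higher and 927 lower in the pair, and DESeq2 called 2512. Of 21 NF-kB and acute inflammation genes, 12 were lower and 0 higher, and 14 passed adjusted over the list alone. The camera adjusted p was 1.09e-40, and the adjusted p was 0.143 with an estimated correlation. The complement gene Cfb, whose product is the substrate of adipsin, was lower in the pair by -4.61 (SE 0.35). Of 28 interferon and antigen presentation genes, 12 were lower, 16 adjusted over the list alone, including Cxcl10 at -2.98 (SE 0.34) and Gbp3 at -2.38 (SE 0.28), at an adjusted p = 0.505 with an estimated correlation.

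Further lists differed by description style, among them those of sterol and beta cell genes. Of 20 cholesterol synthesis genes, 17 were lower in the pair, and all 20 passed adjusted over the list alone, at an adjusted p = 0.258 with an estimated correlation. Mvd stood at -1.13 (SE 0.09), Msmo1 at -0.97 (SE 0.10) and Cyp51 at -0.87 (SE 0.08). Of 29 beta cell identity genes, 6 were higher in the pair and 0 lower, 9 adjusted over the list alone, at an adjusted p = 0.861 with an estimated correlation. They included the incretin receptor Gipr at 1.12 (SE 0.11), Ucn3 at 0.88 (SE 0.19), the glucose transporter Slc2a2 at 0.84 (SE 0.17), the zinc transporter Slc30a8 at 0.64 (SE 0.11) and Iapp at 0.40 (SE 0.08). The lipogenic transcription factor Mlxipl was higher by 0.87 (SE 0.10), and the desaturase Scd2 was lower by -0.92 (SE 0.08), as was the heme oxygenase Hmox1 by -1.06 (SE 0.11). By camera with its preset correlation the mitochondrially encoded, macrophage and acinar lists were lower in the pair too, with medians of -0.67 (adjusted p = 0.00782), -0.67 (0.00782) and -1.32 (0.0317), and each had an adjusted p = 0.861 with an estimated correlation. Of their members, 2 of 8 mitochondrially encoded genes (7 adjusted over the list alone), 2 of 19 macrophage genes and 0 of 26 acinar genes passed. Mitochondrially encoded genes took 1.13% and 1.22% of the counts in the pair and 1.45% to 2.67% in the other 5 libraries.

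Of the 21 pairs of libraries set against the other 5 in this way, 1 gave as many genes, the real pair with 1606. The highest other count was 0, and 1 of 21 is the smallest share this count can give. It does not decide on chance, since it was chosen after the pair had been seen to separate. The difference of that pair also stays in the residual of every other pair. Besides, the 21 pairs include pairs within 1 treatment, unlike the pair that the descriptions define. Depth is argued against, since 1542 genes passed after thinning to the smallest library. A lower share of macrophages in the pair is argued against as the whole cause, since with the macrophage score in the model the log2 differences kept a median of 0.949 of their size for the 12 NF-kB genes and 0.936 for all 1606 genes, although 261 genes then passed, with 1 more term fitted to the 7 libraries. The labels do not say what the description style stands for, and no biological explanation other than the share of macrophages was tested. A difference in islet isolation, culture, animals or sequencing run may lie behind it, and none of these can be separated with the labels at hand.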
